A study of Caenorhabditis elegans with 2 samples.

How the data were processed

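The measurements are chromatin immunoprecipitation followed by sequencing (ChIP-seq) from whole Caenorhabditis elegans embryos. Per the labels, the worms carried an integrated transgene in which HAM-2 is fused at its C-terminal end to GFP and FLAG, together with an unc-119 rescue in an unc-119 mutant background, and the immunoprecipitation used an antibody against GFP. The labels give mixed-stage embryos of 3 hours collected by egg bleaching, of mixed sex, and chromatin sheared by sonication to a size range of 200 to 800 bp. There are 2 libraries, numbered by the submitters as biological replicates 6 and 7 of a single group, each with 1 technical replicate. The design holds no second group, so no contrast between conditions was made.

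Each library has a deposited peak list with background, another list was called on both replicates pooled, and the last holds the peaks that passed the submitters' threshold of irreproducible discovery rate (IDR), called the reproducible set here. Per the deposited listing, each list was made from the replicate alignments and a control alignment. The control library was not analysed here. The assembly is ce11, per the labels. The aligner, the peak caller, their versions and the read depth are not given in the sources used here, so no precision from depth can be given. The signal value of each peak is the one the authors' caller gave and was deposited by them, and its scaling against depth is not stated. It was used to rank peaks within a list and to correlate matched peaks. The deposited −log10 q-value has a single highest value of 3.64 that all 1945 reproducible peaks share, so it was not used to rank them. The p-value column of the lists is empty and was not used. All 1945 reproducible peaks are rows of the pooled list and are exactly its 1945 strongest by signal, with 105.3 as the lowest value, so membership follows the pooled rank. Most peaks have a fixed width given by the caller, 420 bp for 1505 of the 1945.

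Chromosome lengths of the reference used here (WBcel235, the same assembly as ce11) were compared with the lists: in all 24 pairs of list and nuclear chromosome the last peak ended inside the chromosome. Gene models came from Ensembl release 115, with 19973 protein-coding genes on the 6 nuclear chromosomes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Positions are 1-based.

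The tests and gene lists were fixed before the data were examined. Replicate overlap is the share of a list's 1945 strongest nuclear peaks that share at least 1 bp with the other replicate's 1945 strongest, set against 1000 circular shifts of the second list within each chromosome (one-sided permutation test; 100 shifts where whole lists were compared). Signal correlation was taken over peaks matched by summits within 100 bp that overlap the reproducible set, and is descriptive, since peaks are not independent replicates. Each summit was assigned to a promoter (500 bp upstream to 100 bp downstream of the annotated 5′ end of a protein-coding gene), exon, intron or none of these, in that order, and the shares were compared with 1000 circular shifts of the summits (two-sided permutation test). The same shifts tested the share in the middle of each chromosome, its central 50%, and the share within 250 bp of tRNA, snRNA, snoRNA, rRNA and miRNA genes, with Benjamini-Hochberg adjustment over the 5 classes. Chromosome shares were tested with an exact binomial test, two-sided, and intervals are exact Clopper-Pearson intervals at 95%. They cover counting error only. A target gene has a reproducible summit from 1000 bp upstream to 200 bp downstream of its annotated 5′ end. The 22 gene lists were compared with all protein-coding genes by Fisher's exact test, two-sided, adjusted over the lists by Benjamini-Hochberg. Words of 6 bases, counted on either strand, were compared between the 101 bp around each summit and an equal window centred 250 bp downstream, by an exact McNemar test adjusted over 2080 words. The median paired difference in GC content between those windows was tested with 100000 sign permutations.

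Genes named in the text follow a rule set in advance: ham-2, unc-119, egl-43 and egl-5; the nearest target of each of the 12 strongest reproducible peaks that have a target; the 3 members with the strongest peak of each list with more targets than chance; and 1 such member of every other list with a target. The rule gave 36 genes, and its limit of 35 left out fbxb-85. Other genes are named where a count is small, where a peak is shared or as members of a cluster. Those were chosen after their values were seen.

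The procedures were tested on simulated data. Of 100 location and centre tests on uniformly placed peaks, 4% fell under 0.05. Random targets gave 0 list calls in 20 simulated sets of 22 lists, uniform peaks gave 0 noncoding calls in 20 sets, and 3 sets of uniform peaks gave 0.67 called words per set on average. Simulated targets were drawn independently and simulated peaks placed uniformly, while real peaks cluster and neighbouring genes can share a peak. False calls on data of that kind were not measured. A list of 63 homeobox genes set at 3 times the base rate was called in 91% of 100 sets. The simulated base rate was higher than the 4.60% of genes that were targets here, and most lists are smaller. That share therefore does not hold for the real lists, and a list that did not pass may have been missed.

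Alternatives tried were the upper 50% of the reproducible peaks, the 3890 strongest pooled peaks, the 1945 strongest peaks of each replicate alone, other overlap rules, promoter, target and noncoding windows, nearest-gene assignment, circular shifts in place of Fisher's test, and other flanks, window sizes and word lengths. Added after seeing the data were the reproducible set without peaks near noncoding genes, the peaks in both replicates' top lists, and shuffled summit windows as the word background. Peaks on the mitochondrial genome were left out of all tests.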

Results

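ChIP-seq peaks of HAM-2 fused to GFP were available from embryos of 1 group with 2 biological replicates, numbered 6 and 7. HAM-2 is a zinc-finger protein needed for the migration of the HSN motor neurons, in which egl-43 and the Hox gene egl-5 also act. The replicate lists hold 28424 peaks for replicate 6 and 30000 for replicate 7, background included, and the pooled list holds 30000. The reproducible set made by the submitters holds 1945 peaks that cover 728235 bp of the nuclear genome. Signal values are the authors' own and run from 105.3 to 1164 in the reproducible set, with a median of 152.4. Read depth is not given in the sources used here. All positions are on ce11.

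How far the replicates share peaks was the first question. Of the 1945 strongest peaks of replicate 6, 1284 (66.0%, 95% interval 63.9 to 68.1%) overlapped the 1945 strongest of replicate 7, against 1.55% ± 0.298 (SD over 1000 circular shifts). In the other direction 1267 (65.1%) overlapped, against 1.54% ± 0.289. The permutation p was 0.001 in both cases, the smallest that the shifts can give. Of the top 500 of replicate 6, 390 (78.0%) lay in the top 500 of replicate 7. Of the reproducible peaks, 1271 (65.3%) lay in the top lists of both replicates, 414 in that of replicate 6 alone, 215 in that of replicate 7 alone and 45 in neither. Of the 389 strongest, 388 lay in both top lists, and of the 389 weakest 37 did. The weakest lie at the end of a ranked list as long as each top list, so the length of the lists fixes much of this fall. Across 2020 matched peaks, log2 signal in the replicates had a Spearman rho of 0.668 and a Pearson r of 0.748. These values are across peaks, which are not independent replicates, so no p is given.

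**Figure D1:**
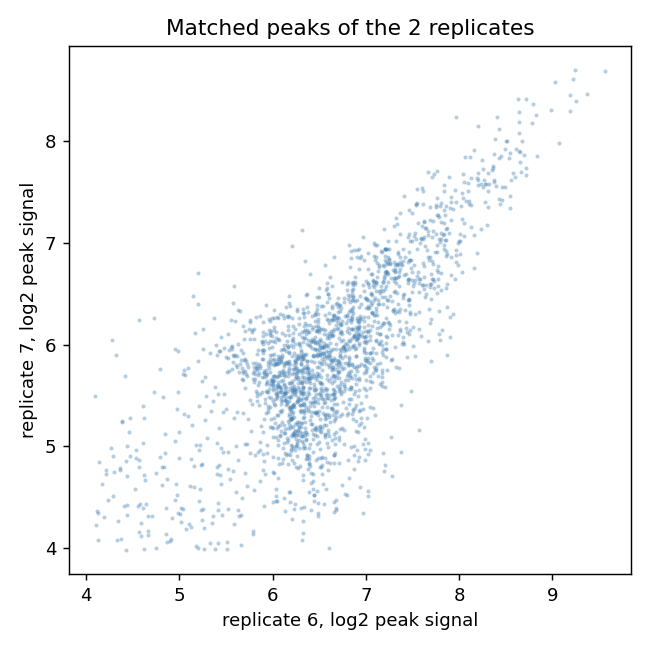
Log2 peak signal in replicate 6 (x axis) and replicate 7 (y axis) for the 2020 matched peaks that overlap the reproducible set, 1 point per peak. Spearman's rho was 0.668 over all points. The reproducible set is a cut on pooled signal, which limits the weak points, and the spread by signal strength was not measured.

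The strongest reproducible peak lay on chromosome X from 5811927 to 5812540, outside any protein-coding gene, with a signal of 1164, rank 1 in replicate 6 and rank 2 in replicate 7. Its nearest annotated 5′ end, that of F13D11.3, was 6255 bp away. The next was on chromosome II from 11960649 to 11961042, with a signal of 1026, within 250 bp of the snoRNA gene W03C9.9. Peak 3 was on chromosome X from 4222662 to 4223128, signal 1009, and 4442 bp from the 5′ end of W01H2.2. Peak 5 lay in an intron of let-526, which encodes a chromatin remodelling subunit, on chromosome I from 5312831 to 5313493. Introns of kin-20, a casein kinase gene, and lin-42, a period homologue of the developmental timing pathway, held peaks 9 and 10, on chromosome X from 15275010 to 15275827 and on chromosome II from 1246810 to 1247259. Of the 38 strongest peaks, 26 had no target gene by the promoter-proximal rule.

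A dense cluster of peaks lay at ham-2 and toward its upstream neighbour C07A12.18. Within 20 kb of ham-2 (WBGene00001821, chromosome X, 4554685 to 4559408, plus strand) there were 9 reproducible peaks, at the 99.97th percentile of protein-coding genes, whose median is 0. They spanned 4548894 to 4556338, with summits from 5581 bp upstream of the annotated 5′ end to 1543 bp inside the gene. The strongest, from 4553049 to 4553460 with its summit 1442 bp upstream, had a signal of 990.0, rank 4 of the set, rank 5 in replicate 6 and rank 3 in replicate 7. The 41 bases around that summit read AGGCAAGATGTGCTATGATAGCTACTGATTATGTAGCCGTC. A further peak 3546 bp upstream had a signal of 770.0 and was nearer to the 5′ end of C07A12.18, at 1236 bp. The peak furthest upstream lay in an intron of C07A12.18, and 2 peaks lay in ham-2 introns, with signals of 204.9 and 360.6. Of the 2 summits inside the target window, the stronger lay 522 bp upstream of the 5′ end with a signal of 273.3, and the other 322 bp upstream with a signal of 119.8. The strain carries a tagged ham-2 transgene, which these lists cannot separate from the endogenous gene. The other gene carried by the transgene, unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935), had 0 reproducible peaks within 20 kb. In the pooled list, which includes background, unc-119 had 26 peaks within that distance (97.2th percentile) with a strongest signal of 79.0, and ham-2 had 23 (93.7th percentile). The nearest reproducible summits to egl-43 and egl-5 were 13331 bp and 40321 bp from their annotated 5′ ends, and neither gene was a target. The chromatin came from whole mixed-stage embryos, so binding limited to a few cells could be missed. This holds for these genes and for the HSN list below.

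**Figure D2:**
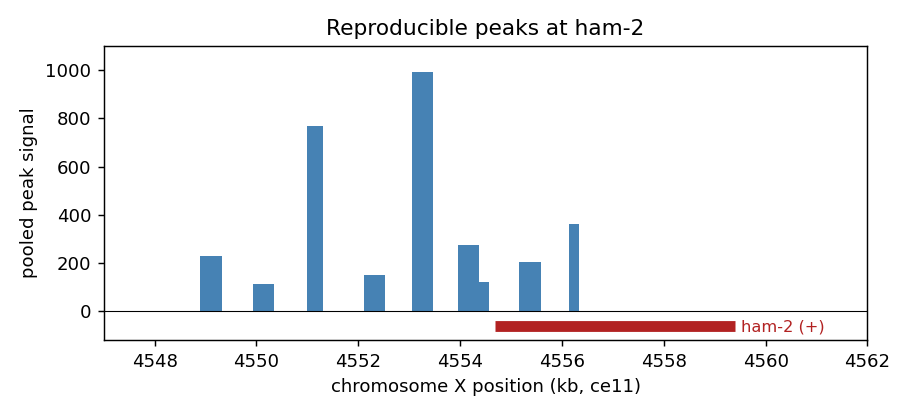
Reproducible peaks at ham-2 on chromosome X: the x axis is the ce11 position in kb, bar height is the pooled peak signal as deposited, bar width is the peak, and the red bar is the annotated gene. The 9 peaks span 4548894 to 4556338, and the highest, at 990.0, lies upstream of the gene.

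Summits were found in promoters more often than shifted positions and in exons far less often. Promoters held 540 summits (27.8%), against 10.9% ± 0.730 (SD over shifts), a ratio of 2.56. Exons held 71 (3.65%) against 26.3% ± 1.08, a ratio of 0.139. Introns held 571 (29.4%) against 32.8% ± 1.10. Outside protein-coding genes and their promoters lay 763 (39.2%), against 30.0% ± 1.12, and noncoding genes count as outside here. Each of the 4 permutation p-values was 0.002, the smallest that the 1000 shifts can give. The exon share was 10.5% among the 1945 strongest peaks of replicate 7 and 3.50% among those of replicate 6, both below the shifted share.

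**Figure D3:**
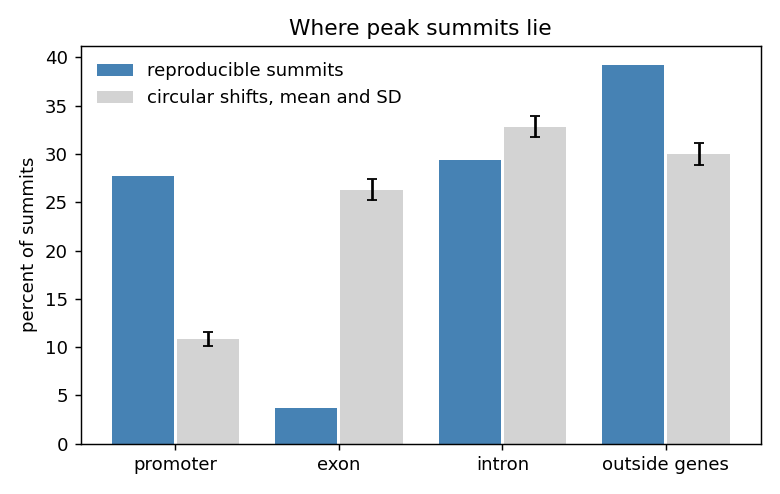
Percent of summits in promoters, exons, introns and outside protein-coding genes. Blue bars are the 1945 reproducible summits, and grey bars are circularly shifted summits (mean with SD over 1000 shifts). Promoters stand at 27.8% against 10.9%, and exons at 3.65% against 26.3%.

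Peaks were unevenly spread over the chromosomes. Chromosome X held 491 of the 1945 (25.2%, 95% interval 23.3 to 27.2%), or 27.7 per Mb, against 17.7% of the genome length (exact binomial p = 6.39e-17) and 13.7% of the protein-coding genes (p = 6.94e-42). Chromosome III held 321 (16.5%) against 13.7% of the length (exact p = 0.000542). Chromosome V held 240 (12.3%, 11.5 per Mb) against 20.9% (exact p = 9.53e-23), and chromosome IV held 257 (13.2%) against 17.4% (p = 4.26e-07). The shares of chromosomes I (16.6%) and II (16.1%) did not pass the length test (exact p = 0.0530 and 0.298). These p-values are not adjusted over the 6 chromosomes, and the binomial test treats peaks as independent, which clusters such as that at ham-2 are not. The central 50% of the chromosomes held 56.0% of summits against 50.1% ± 1.89 under shifts (permutation p = 0.002, the smallest possible).

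Short noncoding genes were strongly represented. Summits within 250 bp of a tRNA gene numbered 165 (8.48%, against 0.367% ± 0.137 under shifts, ratio 23.1), and 179 of 612 tRNA genes had such a summit. For snoRNA genes there were 66 summits (3.39%, ratio 15.7), for snRNA genes 15 (0.771%, ratio 11.8) and for miRNA genes 13 (0.668%, ratio 4.42). The permutation p was 0.002 for each of these 4 classes, 0.0025 after Benjamini-Hochberg adjustment over the 5 classes. None of the 20 annotated rRNA genes had a summit nearby, where 0.0145% of shifted summits fell.

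Target genes numbered 919 of 19973 (4.60%), against 433.0 ± 20.1 under shifts (permutation p = 0.002). Among the 22 lists, ribosomal protein genes had 24 targets of 76 (31.6%, 95% interval 21.4 to 43.3%, 6.86 times the share of all genes, Fisher's exact adjusted p = 2.55e-13). When each summit was given to its nearest gene instead, the list had 15 of 76 (ratio 2.69, exact adjusted p = 0.00159), below the ratios of the epidermal (6.81, 15 of 30), axon guidance (4.89), body muscle (3.41) and Wnt pathway (3.27) lists. That rule takes summits up to 5000 bp from a 5′ end, introns included. Fisher's test does not adjust for the space around each gene, so genes with more space can gain summits under it. The strongest ribosomal protein targets were rpl-3 (chromosome III, peak 3867451 to 3867719, signal 534.5), rpl-7 (chromosome I, 110560 to 110813, signal 491.5) and rpl-20 (chromosome IV, 4749935 to 4750175, signal 350.7), each with its summit upstream of the 5′ end by 269, 359 and 281 bp. The peaks at rpl-7 and rpl-20 also lie in the target windows of rab-11.1 and Y17G9B.5. The targets rpl-39 and rps-30 share a peak. No library from an untagged strain is at hand. Signal at highly transcribed loci whatever the tagged protein therefore stays open for this list and the other lists.

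Of 30 epidermal genes, which build the worm's skin and cuticle, 8 were targets (26.7%, 12.3 to 45.9%, ratio 5.80, exact adjusted p = 0.000254). The strongest peak was at che-14, needed for apical secretion, with its summit 66 bp upstream of the 5′ end (chromosome I, 5746395 to 5746711, signal 631.2, rank 18 in replicate 6 and 44 in replicate 7). The cuticle collagen gene dpy-10 had a peak at chromosome II, 6713127 to 6713301 (signal 264.7), which is also in the window of T14B4.19, and the hedgehog-related gene wrt-2 had one at chromosome X, 3094328 to 3094747 (signal 231.8). The other 5 were nhr-23, dpy-13, dpy-3, dpy-7 and wrt-1. A separate collagen list, whose targets were all col genes, holds none of the dpy targets named here, so it does not bear on them. It did not pass, with 7 targets of 156 (ratio 0.975, exact adjusted p = 1). Nor did it pass where its ratio was above 1, as among peaks in both top lists (1.33, exact adjusted p = 0.734).

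Of 60 chaperone genes, 12 were targets (20%, 10.8 to 32.3%, ratio 4.35, exact adjusted p = 0.000112), led by hsp-60 (chromosome III, 1618898 to 1619317, signal 241.7), hsp-3 (chromosome X, 6092044 to 6092173, signal 231.5) and dnj-29 (chromosome I, 14113069 to 14113488, signal 192.0). The list did not pass among the upper 50% of peaks, with a ratio of 2.74 and an exact adjusted p of 0.160, and by nearest gene it had 10 of 60 (ratio 2.27, exact adjusted p = 0.0279). The heat-inducible pair hsp-16.2 and hsp-16.41 share a peak, and cct-1 shares one with mig-5. The hsp-60 peak also lies in the target window of Y22D7AL.10, and the dnj-29 peak in those of ndua-2 and fld-1.

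Fewer targets than chance were found in large, fast-evolving families. Chemoreceptor genes had 8 targets of 1364 (0.587%, 0.254 to 1.15%, ratio 0.127, exact adjusted p = 9.04e-18), and F-box genes had 4 of 322 (1.24%, ratio 0.270, exact adjusted p = 0.00766). In replicate 7 alone the F-box list had 1 of 322 (ratio 0.0810, exact adjusted p = 0.000519). The 4 F-box genes were fbxb-85, fbxc-44, fbxa-153 and fbxb-66. Against circular shifts in place of all other genes, where all protein-coding genes together stand at a ratio of 2.12, the F-box list did not pass (ratio 0.579, permutation adjusted p = 0.622), nor with a window of 500 bp upstream to 100 bp downstream (ratio 0.383, exact adjusted p = 0.119). The strongest chemoreceptor peak, at sre-23 (chromosome I, 8259404 to 8259725, signal 705.5), lies within 250 bp of the snoRNA gene ZK265.10.

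**Figure D4:**
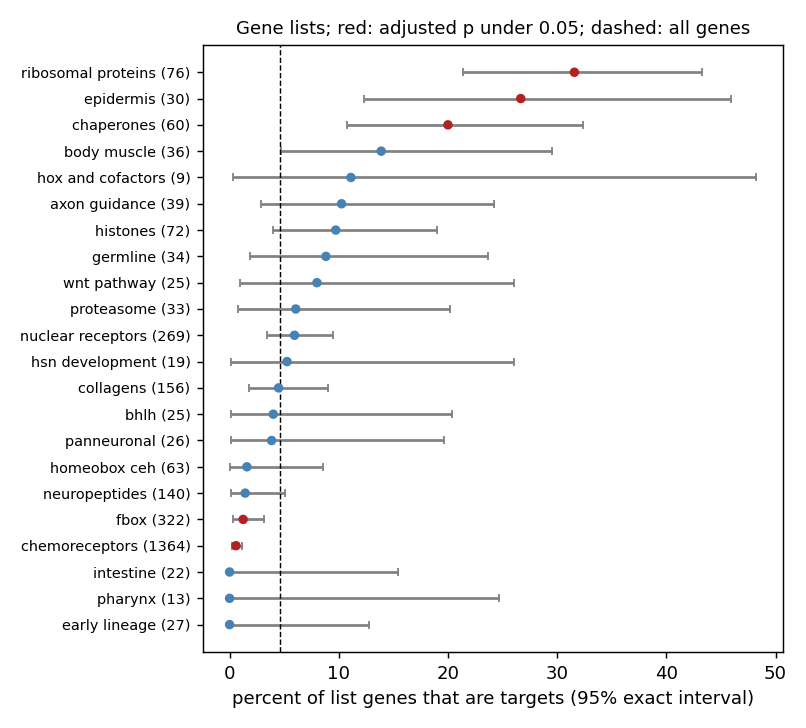
Percent of each gene list's members that were targets (x axis), with exact 95% intervals and the number of genes in brackets, 1 point per list; red points have an adjusted p under 0.05 and the dashed line is the 4.60% of all protein-coding genes. Ribosomal protein, epidermis and chaperone genes lie above the line, and chemoreceptor and F-box genes below it.

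By the promoter-proximal rule and against all genes, the neuronal and developmental lists did not pass, but axon guidance, Wnt pathway and nuclear receptor genes passed under other settings. The HSN list had 1 target of 19, ham-2 itself (ratio 1.14, exact adjusted p = 0.811). It had 2 of 19 in replicate 7 alone (ratio 2.74, exact adjusted p = 0.328), 1 of 19 in replicate 6 alone and 3 of 19 by nearest gene (ratio 2.15, exact adjusted p = 0.292). The Hox and cofactor list had 1 of 9, ceh-20 (exact adjusted p = 0.582, chromosome III, 6978748 to 6979167, signal 210.9), and the panneuronal list 1 of 26, the presynaptic gene syd-2 (chromosome X, 10555686 to 10555828, signal 270.3). The homeobox list had 1 of 63, again ceh-20 (ratio 0.345, exact adjusted p = 0.582), neuropeptide genes 2 of 140, flp-23 and flp-14 (exact adjusted p = 0.252), and the early lineage list 0 of 27 (exact adjusted p = 0.811). Axon guidance genes had 4 of 39 (ratio 2.23, exact adjusted p = 0.252): unc-73, unc-115, unc-33 and smp-2. They passed with a window of 2000 bp upstream to 500 bp downstream (9 of 39, ratio 3.35, exact adjusted p = 0.00344), by nearest gene (14 of 39, ratio 4.89, exact adjusted p = 2.39e-06), but not with a window of 500 bp upstream to 100 bp downstream (2 of 39, ratio 1.58, exact adjusted p = 0.771) or in replicate 7 alone (ratio 3.34, exact adjusted p = 0.0504) or replicate 6 alone (ratio 2.14, exact adjusted p = 0.317). Wnt pathway genes had 2 of 25, mig-5 and mig-14 (exact adjusted p = 0.582), and 6 of 25 both with the wider window (ratio 3.48, exact adjusted p = 0.0165) and by nearest gene (ratio 3.27, exact adjusted p = 0.0224). They had 0 of 25 in replicate 7 alone, in the upper 50% of peaks and among peaks in both top lists, and 1 of 25 in replicate 6 alone (ratio 0.834, exact adjusted p = 1). Basic helix-loop-helix genes had 1 of 25, hlh-2 (exact adjusted p = 1, chromosome I, 7194713 to 7194980, signal 384.2), and nuclear receptors had 16 of 269 (ratio 1.29, exact adjusted p = 0.582), with nhr-255 strongest at a peak within 250 bp of a tRNA gene. Nuclear receptors passed by nearest gene (35 of 269, ratio 1.77, exact adjusted p = 0.00291), and with the wider window they had a ratio of 1.08 (exact adjusted p = 0.787). Against circular shifts, axon guidance (ratio 4.62), nuclear receptor (3.53), body muscle (5.89) and histone genes (5.28) passed, but this setting has no comparison with other genes, and all genes together stand at 2.12. Other ratios turned without passing: homeobox genes had 8 of 63 among the 3890 strongest pooled peaks (ratio 1.57, exact adjusted p = 0.333), the panneuronal list 4 of 26 with the wider window (ratio 2.23 from 0.836, exact adjusted p = 0.200), and the early lineage list 3 of 27 by nearest gene (ratio 1.51, exact adjusted p = 0.613). The Hox and cofactor list had 0 of 9 with the narrower window. In single replicates, basic helix-loop-helix genes had 2 of 25 in each, the panneuronal list 2 of 26 in replicate 6, and neuropeptide genes 3 of 140 in replicate 7 and 1 of 140 in replicate 6, and none of these passed (lowest exact adjusted p = 0.0570).

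Among the other tissue lists, body muscle had 5 targets of 36 (ratio 3.02, exact adjusted p = 0.0864): unc-60, unc-112, pat-4, unc-54 and atn-1. This list passed in replicate 7 alone (7 of 36, ratio 5.07, exact adjusted p = 0.00165) and not in replicate 6 alone (3 of 36, ratio 1.74, exact adjusted p = 0.496), and the difference between the replicates was not tested. It also passed among the 3890 strongest pooled peaks (9 of 36, ratio 3.09, exact adjusted p = 0.00578), with target windows of 500 to 100 bp (ratio 4.29, exact adjusted p = 0.0254) or 2000 to 500 bp (ratio 3.63, exact adjusted p = 0.00215) and by nearest gene (ratio 3.41, exact adjusted p = 0.00291). It did not pass in the upper 50% of peaks (ratio 3.42, exact adjusted p = 0.160), without peaks near noncoding genes (ratio 3.26, exact adjusted p = 0.0642) or among peaks in both top lists (ratio 2.87, exact adjusted p = 0.235). Germline genes had 3 of 34, cgh-1, mex-1 and spn-4 (exact adjusted p = 0.450), and the intestine and pharynx lists had 0 of 22 and 0 of 13 (exact adjusted p = 0.811 and 1). Histone genes had 7 of 72 (ratio 2.11, exact adjusted p = 0.149), with his-67 and his-68 sharing the strongest peak. They passed among the 3890 strongest pooled peaks (14 of 72, ratio 2.40, exact adjusted p = 0.00578), but had 5 of 72 by nearest gene (ratio 0.946, exact adjusted p = 1), 2 of 72 in the upper 50% of peaks (ratio 1.14, exact adjusted p = 0.900) and 3 of 72 among peaks in both top lists (ratio 1.44, exact adjusted p = 0.734). Proteasome genes had 2 of 33, pbs-7 and pbs-4 (exact adjusted p = 0.811). The germline ratio turned from 1.92 to 0.801 by nearest gene and the proteasome ratio from 1.32 to 0.935 with the window of 500 to 100 bp, without passing. In replicates 7 and 6 alone, proteasome genes had 3 and 4 of 33, germline genes 2 of 34 in each, and the pharynx list 1 and 0 of 13, and none of these passed (lowest exact adjusted p = 0.225).

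Of the strongest peaks that had a target gene, the first was at bet-2, a bromodomain gene (chromosome X, 10568505 to 10569040, signal 902.9, ranks 9 and 4 in replicates 6 and 7), and the next at mdl-1, a Mad-family transcription factor gene (chromosome X, 6741692 to 6742365, signal 889.0, ranks 6 and 12), with summits 453 and 267 bp upstream of the 5′ ends. Peaks with signals from 590.0 to 705.5 followed at sre-23, unc-73, T02E1.2, hpo-2, din-1, che-14, atf-2, ain-1, F55A11.11 and unc-14. The gene unc-73 encodes a guanine nucleotide exchange factor of axon guidance, din-1 a corepressor, atf-2 a bZIP factor and ain-1 a microRNA silencing cofactor. The peaks of sre-23, T02E1.2 and F55A11.11 are within 250 bp of a snoRNA gene.

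The sequence at summits differed from that of the flanks. Mean GC content was 49.4% ± 7.26 (SD over 1945 windows) at summits and 36.9% ± 8.84 in the flanks. The median paired difference was 12.9 points, with 1666 of 1945 peaks higher at the summit (permutation p = 1e-05, the smallest that the permutations can give). Of 2080 words of 6 bases, 688 were more frequent and 480 less frequent at summits (exact McNemar test, Benjamini-Hochberg adjusted p under 0.05). The words less frequent at summits were led by A and T runs, such as AAAAAT, in 11.6% of summit windows and 42.3% of flanks. Among those more frequent, GAGAGA came first, in 489 summit windows (25.1%) and 180 flanks (9.25%, exact adjusted p = 1.27e-39). AGAGAC was in 337 against 108, CGTCTC in 286 against 88 and CGCAGA in 226 against 57. Because GC content itself differs, the summit windows were also compared with their own dinucleotide shuffles, an alternative added after seeing the data, and 169 words were then more frequent at summits. GAGAGA remained first (489 against 192 windows, exact adjusted p = 4.54e-44), while AAAAAT no longer differed (ratio 1.04, exact adjusted p = 0.852). AAAAAT is a single word and does not stand for the others less frequent at summits. Shuffling keeps dinucleotide counts but not their order, so it can break up simple repeats in any window. CACACA came second in that comparison (300 against 105 windows). The flanks were not compared with their own shuffles, so that setting does not show that the excess of GAGAGA is particular to summits. Among words of 8 bases, AGACGCAG was in 147 summit windows and 25 flanks (exact adjusted p = 3.60e-19), and in 7 shuffled windows.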

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

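For the patterns below, 3 tests were chosen after their result was seen: the untagged-strain row, the repeated tRNA sequences and the long telomere-type runs. The other tests had their bounds written before their results were seen, on patterns already noticed in these data, and the tRNA and telomere-type patterns were split by copy number and run length after those tests had been read. The design holds a single group, so no biological explanation was tested for any of them.

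A signal outside the nuclear comparisons was found in the replicate 6 list, which holds 10 peaks on the mitochondrial genome. Replicate 7 and the pooled list, which includes replicate 6, hold 0, and whether these 0 counts come from how the lists were made was not tested. The strongest, at mitochondrial positions 5347 to 5776, has a signal of 396.7 and rank 29 in that list, and 9 of the 10 fall among its 1945 strongest peaks.

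The cluster of 9 reproducible peaks at ham-2 may reflect binding at the region upstream of the gene, which also borders C07A12.18, or extra copies of the tagged transgene. If extra copies raised a whole inserted segment, weak peaks near ham-2 would be raised too. The median signal of the 14 weak pooled peaks within 20 kb was 40.2, against a median of 38.9 over 17508 genes, at the 61.5th percentile. That lies between the bound of 95 set for the copies and the bound of 50 set against them. The explanations therefore cannot be told apart with these lists. Weak peaks here are those below 105.3, the lowest reproducible signal. Any peak that extra copies raised past that value was left out, so this percentile says little about copy number. The control alignment used by the submitters may remove copy number in part, which was not tested.

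Peaks at tRNA genes were 23.1 times as frequent as under shifts. GC-rich sequence alone is argued against: among 100 draws of positions matched in GC content, the highest share near a tRNA gene was 1.23%, against 8.48% at summits. Of tRNA genes whose whole sequence occurs once in the genome, 25 of 140 (17.9%, 95% interval 11.9 to 25.2%) had a summit. This argues against copies identical over the whole gene as the only source. Such genes may still share shorter stretches with near copies or lie beside a repeated tRNA gene, which was not tested. Shared reads may add to the others, of which 154 of 472 (32.6%) had a summit (Fisher's exact p = 0.000673). Signal at highly transcribed loci whatever the tagged protein stays open, because 0 libraries from an untagged strain are at hand.

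Telomere-type repeats, with 3 or more TTAGGC units on either strand in the 101 bp around the summit, were found at 107 peaks (5.50%), while the highest of 100 GC-matched draws was 1.13%, which argues against GC content alone. If reads from chromosome ends were placed on interstitial copies without mismatches, long perfect runs would be hit and short ones would not. Sites with at most 3 units in a row had a summit in 76 of 1625 cases (4.68%, interval 3.70 to 5.82%) against 0.546% under shifts. This argues against perfectly matched reads from longer telomeric repeat at these sites. Reads placed with mismatches are not excluded, because the aligner is unknown and such sites may hold imperfect units. The share was higher at 4 or 5 units in a row, 32 of 190 (16.8%). At 6 or more it was 10 of 41 (24.4%, Fisher's exact p = 0.000154 against shorter runs), so misplaced reads may contribute there.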

How the results depend on the processing

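Of 369 values under other settings, 303 kept their direction and their side of the threshold or, for counts, stayed within 1.5 times the main count. For a list that did not pass, this says only that it still did not, in the same direction, and not that its ratio was stable. The direction turned in 38, none of which passed under the setting where it turned, and of these AAAAAT alone had passed in the main setting. The shuffled-window setting and the sets without noncoding peaks or in both top lists were chosen after seeing the data. Location, chromosome X, chromosome centre, noncoding and GC results passed their tests in the main direction under every setting tried for them, including each replicate alone. The gene lists depended on the peak set, the target rule and the background. With more targets than chance, 3 lists passed in the main setting, 5 with the 3890 strongest pooled peaks, 6 with a target window of 2000 bp upstream to 500 bp downstream, 7 by nearest gene and 7 against circular shifts. The lists gained were body muscle in each of these 4, axon guidance in the last 3, Wnt pathway with the wider window and by nearest gene, nuclear receptors by nearest gene and against shifts, and histones with the 3890 peaks and against shifts. The wider window and the larger set give more targets. Nearest-gene assignment favours genes with more space around their 5′ ends, for which Fisher's test does not adjust. The shifts compare with the genome instead of other genes, and all genes together have a ratio of 2.12 there. With fewer targets, 2 lists passed in the main setting, 1 with the window of 500 to 100 bp and 1 against shifts, the F-box list being lost both times (ratios 0.383 and 0.579). Chaperones were lost in the upper 50% of peaks (ratio 2.74, from 4.35), where fewer targets are tested. Ratios of lists that passed in neither setting turned as follows. Wnt pathway (main 1.74) had 0 in the upper 50% of peaks and in both top lists, 0.989 with the 3890 peaks, and 0 to 0.834 without 1 replicate. Panneuronal genes (0.836) had 1.58 in the upper 50%, 1.43 with the 3890, 1.33 in both top lists, 1.19 with the narrower and 2.23 with the wider window, 2.10 by nearest gene, 1.59 against shifts and 1.003 to 1.60 without 1 replicate. Basic helix-loop-helix genes (0.869) had 1.64, 1.48 and 1.38 in those 3 peak sets, 1.09 by nearest gene, 1.68 against shifts and 1.67 to 2.09 without 1 replicate. Collagens (0.975) had 1.32, 1.27 and 1.33 in those sets, 1.21 with the wider window, 1.31 by nearest gene, 2.02 against shifts and 1.003 to 1.07 without 1 replicate. Homeobox genes (0.345) had 1.57 with the 3890 peaks, and the pharynx list (0) 0 to 2.01 without 1 replicate. With the narrower window Hox (2.41) had 0, germline (1.92) 0.908 and proteasome genes (1.32) 0.935. By nearest gene early lineage (0) had 1.51, germline 0.801 and histones (2.11) 0.946. The cause of these turns was not tested. The words more frequent at summits fell from 688 to 169 with shuffled windows, which keep base composition. AAAAAT turned from a ratio of 0.274 to 1.04, which does not speak for the other words less frequent at summits. Words of 8 bases gave 727 less frequent at summits in place of 480, but 478 more frequent in place of 688, and the cause was not tested. Far more words of 8 bases were tested than the 2080 of 6 bases, so these counts are not shares of the same whole. Spearman's rho between replicates was 0.707 with summits within 50 bp and 0.561 over all matched peaks, and the cause was not tested. Read depth is not given, so its limits cannot be stated.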

Other observations

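All tests in this part were chosen after seeing the data, and their values are descriptions of these lists.

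Gene classes by name prefix, 175 with at least 10 members, were compared with all genes by Fisher's exact test, adjusted by Benjamini-Hochberg. Besides the ribosomal protein classes rpl and rps, the dpy class of body-shape genes had 9 targets of 25 (ratio 7.82, exact adjusted p = 5.44e-05) and the lin class of cell lineage genes 10 of 47 (ratio 4.62, exact adjusted p = 0.00194), among them lin-14, lin-53, lin-54 and lin-9. The mig class of cell migration genes had 5 of 16, mig-15, mig-38, mig-5, mig-14 and mig-22 (ratio 6.79, exact adjusted p = 0.0170), and the rab class of small GTPases 5 of 20 (ratio 5.43, exact adjusted p = 0.0310). The hedgehog-related wrt class had 4 of 10 (exact adjusted p = 0.0187). The unc class, named for uncoordinated movement, had 12 of 94 (ratio 2.77, exact adjusted p = 0.0272), and the heat shock class hsp 5 of 22 (ratio 4.94, exact adjusted p = 0.0407). Targets of the dpy, wrt, hsp, mig and unc classes include genes already counted in the epidermal, chaperone, Wnt pathway, axon guidance and body muscle lists. These classes are therefore not independent of those lists. Classes with fewer targets than all genes were lectin-type clec, 2 of 240 (ratio 0.181, exact adjusted p = 0.0310), and the chemoreceptor classes srh, 1 of 220, srh-269 (ratio 0.0988, exact adjusted p = 0.0170), and str, 1 of 193, str-12 (ratio 0.113, exact adjusted p = 0.0407).

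Counting summits from 5 kb upstream of a gene to its far end, ham-2 had the most of all protein-coding genes, 8. Its neighbour C07A12.18 followed with 7, which belong to the same cluster of peaks, so the 2 counts are not separate. Next, with 6 each, were kin-20, Y67D8A.2, lit-1, zfp-1 and Y111B2A.12. In all, 10 genes had 5 or more.

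Some peaks were in only 1 replicate's 1945 strongest. A Fisher's exact test of their exon shares was run over peaks, but it compares 2 single libraries and peaks are not independent replicates, so it is not used and the values are descriptions. Of the 678 in replicate 7 alone, 148 (21.8%) had a summit in an exon, against 19 of the 661 (2.87%) in replicate 6 alone, and promoters held 15.6% against 32.98%. Mean GC content at their summits was 49.4% ± 7.50 and 45.8% ± 7.24 (SD).

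The telomere-type peaks lay toward chromosome ends: 11.2% of the 107 were in the central 50% of a chromosome, and 2 were on X. Where the repeat itself lies was not counted, so this placement cannot be told apart from that of the repeat. No telomere-type peak was within 250 bp of a tRNA gene. Of the 107, 26 fell in the stronger 972 peaks and 81 in the others (Fisher's exact p = 4.13e-08). The word AGACGCAG was in 39 of 540 promoter peaks (7.22%) and 108 of 1405 others (7.69%, Fisher's exact p = 0.774), and its median distance from the summit was 19 bp. Of 276 tRNA genes on X, 30.1% had a summit, against 28.6% of 336 on autosomes (Fisher's exact p = 0.721). Without peaks near noncoding genes the share of peaks on X was 24.3%, against 25.2% with them.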
